A study of Mus musculus with 8 samples.

How the data were processed

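The series holds RNA sequencing of 8 mouse colon tumours from animals treated with azoxymethane, a colon carcinogen. According to the series design, 1 whole tumour was taken from each mouse, so the 4 Trp53ΔIEC and the 4 Trp53ΔIECAktE17K tumours come from 8 separate mice. P-values of single genes, of fry and of list scores, described below, therefore apply to variation between mice of these groups. Those of camera compare a list's genes with other genes and depend on the correlation set between genes, so they do not measure variation between mice alone. In the field's notation ΔIEC stands for loss of the gene in intestinal epithelial cells, and E17K is an activating substitution of the kinase AKT. RNA was extracted with the RNeasy Mini Kit and libraries were made with the TruSeq mRNA v2 kit, which selects polyadenylated RNA and does not record the strand. Each group has 4 libraries, and no library was left out of the comparison.

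The deposited values are counts: the authors deposited, for each tumour, the number of reads assigned to each Ensembl gene, with no normalisation. The submitters' processing notes name the mouse build mm10 and the tools CASAVA 1.8.2, STAR 2.3.0, SAMtools 1.2, HTSeq 0.6 and DESeq2 1.8.1, without stating what each was used for. The annotation release, the strand setting and any read filter are not given in the sources used here. Each table has 38355 genes and 5 closing lines that count reads not assigned to a gene, which were set aside. Reads in no annotated feature came to 9.74% to 11.7% of the uniquely aligned reads and reads overlapping more than 1 gene to 1.93% to 2.32%. Alignments of reads with several places in the genome came to 0.693 to 0.916 per assigned read, and the lines for low alignment quality and for unaligned reads held 0 in every library. Because such reads are not counted for any gene, levels of near-identical genes (Hba-a1 and Hba-a2, Krt6a and Krt6b, the Mup and Cyp2c families, the H2 genes) rest on the reads that differ between them. Gene symbols, positions and types were taken from GENCODE M21 on GRCm38, which held 36602 of the 38355 identifiers (95.4%). None of the 13 listed mitochondrially encoded genes is in the tables.

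The assigned reads per tumour ranged from 18572180 to 26268547. Bounds are given for genes selected by the naming rule described below. Where a group had 0 counts of such a gene, the fold is a lower bound against a floor of 3 counts over the group. Where it had 1 to 3 counts, the ratio of counts is given with its 95% exact (Clopper-Pearson) interval. These limits cover counting error only, since reads amplified by PCR without molecular identifiers are not independent molecules.

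Differential expression was tested with edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr with default settings, library sizes were scaled by TMM, and the quasi-likelihood F-test with robust dispersions was fitted with the group as its only term. P-values were adjusted with the Benjamini-Hochberg procedure over the 16539 genes tested, and genes with an adjusted p under 0.05 were called. All fold changes are Trp53ΔIECAktE17K over Trp53ΔIEC, and levels are given as CPM (counts relative to the library size after TMM scaling), as mean ± SD over the 4 tumours of a group. The labels name no batch, litter or day. The letter in the sample titles is A for Trp53ΔIECAktE17K replicates 1 and 2 and B for the other 6 tumours, whereas the codes of the deposited tables give A to all 4 Trp53ΔIECAktE17K tumours. What the letter stands for is not given, and it was tried as a term.

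There are 54 gene lists, written from general knowledge of colon and tumour biology. For each list with at least 5 tested members, edgeR's camera with a preset inter-gene correlation of 0.01 compared the members with all other genes, with Benjamini-Hochberg adjustment over the 50 such lists. Camera with a correlation estimated per list, and fry from limma 3.58.1, which tests whether a list's genes move on balance one way without comparing them with other genes, were run beside it. For each tumour a list score was computed as the mean log2 CPM (prior count 2) of the tested members and compared by a two-sided exact permutation test over the 70 assignments of 8 tumours, whose smallest possible p is 0.0286. Within each list, p-values were also adjusted over the list alone.

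Genes named in the text were fixed by a rule. It takes Trp53, the Akt genes and the 4 Notch receptors. It adds the 10 higher and the 10 lower called genes with the largest fold change, an average log2 CPM of at least 1 and no overlap between the groups, leaving out predicted models and antigen receptor segments. From each list it takes up to 4 members with the smallest adjusted p, or the 2 with the smallest unadjusted p where none passed. Some of the genes it selects are not reported here. Other genes are named as chosen after their values were seen. The grouping, the tests, the gene lists, the rule for named genes and the alternatives, except those said to be added later, were fixed before the data were examined.

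The tools were tested on simulated data of 8 libraries with the mean counts and spread of these tumours. With 100 of 16539 genes changed 4-fold, edgeR recovered 56%, DESeq2 82% and limma-voom 52%, and with 100 changed 2-fold they recovered 6%, 34% and 3%. False calls numbered 2 for edgeR, 81 for DESeq2 and 3 for limma-voom. Camera, camera with an estimated correlation and fry each found both changed lists and called 0 of 50 unchanged lists. The simulated genes were drawn independently of each other, whereas the estimated correlation was, for example, 0.93 in the MHC class II list. The simulation therefore does not check the set tests on lists of correlated genes.

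Alternatives tried were DESeq2's size factors, upper-quartile factors, library sizes without the 10 most abundant genes, DESeq2 1.42.0 and limma-voom as tests, no low-count filter, a filter of at least 5 CPM in 4 libraries, non-robust dispersions, a term for the replicate number, thresholds of 0.01 and 0.10, and leaving out each tumour in turn. Runs without Trp53ΔIECAktE17K replicates 1 and 4, without cardiac muscle and hepatocyte genes, with the letter of the sample titles as a term, and with the replicate term and an estimated correlation together were added after the data had been seen. Lists of cardiac muscle, hepatocyte, kidney, brain and lung genes were also written then. Tables and figures were made with Python 3.11.15, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.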

Results

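RNA was measured in 8 whole colon tumours from azoxymethane-treated mice, 4 with the Trp53ΔIEC genotype and 4 with the Trp53ΔIECAktE17K genotype, with 1 tumour per mouse. Reads assigned to genes numbered 25842173, 26268547, 18572180 and 21844835 in Trp53ΔIEC replicates 1 to 4, and 23417086, 23654913, 23074876 and 22568555 in Trp53ΔIECAktE17K replicates 1 to 4. Between 21173 and 22597 genes had at least 1 read in a tumour. The pairwise correlation of log2 CPM ranged from 0.94 to 0.966 within Trp53ΔIEC tumours, from 0.896 to 0.957 within Trp53ΔIECAktE17K tumours and from 0.873 to 0.937 between the groups. On the first principal component, which held 39.8% of the variance, the Trp53ΔIEC tumours lay between -59.6 and -49.7 and the Trp53ΔIECAktE17K tumours between 20.4 and 80.6.

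The comparison of Trp53ΔIECAktE17K with Trp53ΔIEC tumours asks what active AKT adds to colon tumours that lack Trp53 in the epithelium. The series title names NOTCH3 activation and a mesenchymal tumour subtype as its subject. In the Trp53ΔIECAktE17K tumours 13 of 22 tested fibroblast and fibrillar matrix genes, 8 of 14 smooth muscle genes, 4 of 9 pericyte genes and 5 of 9 enteric glia and neuron genes were higher, with 4-fold to 14-fold differences for the smooth muscle genes Cnn1, Des, Tagln and Actg2. Camera called these 4 lists higher, but not with an estimated correlation (adjusted p = 0.186, 0.156, 0.227 and 0.156). The receptor gene Notch3 was 3.13-fold higher, from 9.83 ± 1.71 CPM to 30.8 ± 17.3 CPM, while Notch1, Notch2 and Notch4 did not pass the test. Of 12 tested squamous epithelium markers 4 rose, among them Krt5, by very different amounts in single tumours, and limma-voom called 0 of them. The stem cell gene Ascl2 and Srebf2, a regulator of cholesterol synthesis, were lower. With 1 tumour left out in turn, Notch3, Ascl2 and Srebf2 kept their calls in 2, 1 and 2 of the 8 runs. Of 34 tested heart muscle genes 25 were higher, such as Myh6, with nearly equal levels in all 4 Trp53ΔIECAktE17K libraries. Of 30 tested hepatocyte genes 10 were lower, such as Crp, with nearly equal levels in all 4 Trp53ΔIEC libraries, and 1 was higher. The heart muscle and hepatocyte lists were written after the data had been seen.

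Of 16539 genes tested, 694 had an adjusted p under 0.05 (edgeR quasi-likelihood, Benjamini-Hochberg), 569 of them higher and 125 lower in Trp53ΔIECAktE17K tumours, and 3446 had an unadjusted p under 0.05. More than 2-fold changes made up 540 of the higher and 61 of the lower genes, while the median log2 fold change of all tested genes was 0.01. The groups did not overlap in 691 of the 694 genes, nor in any of the 74 called genes that the naming rule selects. For its 10 higher and 10 lower genes the rule itself requires this. Over all tested genes 14.2% had no overlap, where chance gives 2.86%. DESeq2 called 1715 higher and 764 lower genes. The counts changed when 1 tumour was left out, which also leaves fewer residual degrees of freedom. Without Trp53ΔIEC replicates 1, 2, 3 and 4 in turn they were 217, 64, 72 and 67 higher and 37, 10, 14 and 12 lower. Without Trp53ΔIECAktE17K replicates 1, 2, 3 and 4 in turn they were 155, 252, 567 and 702 higher and 25, 37, 98 and 247 lower. Across the 8 removals 55 of the 694 genes stayed called each time, 24 of them genes of the cardiac muscle and hepatocyte lists.

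Camera called 28 of the 50 gene lists tested. With an estimated correlation it called 0, with 8 lists at an unadjusted p under 0.05, and fry called 11. Fry's 11 were the Notch target, mesenchymal, fibroblast, smooth muscle, pericyte, enteric glia and neuron, enteroendocrine, YAP, erythroid, mTORC1 and ATF4, and stem cell lists. Every other list, including the rest of those that camera called, had a fry adjusted p of at least 0.0605. List scores per tumour differed with an exact permutation p of 0.0286, the smallest that this design allows, in 13 lists, and after adjustment over the lists the smallest p was 0.11. That p arises only where the 4 tumours of each group lie on their own side. The 13 lists were the Notch target, mesenchymal, fibroblast, TGF-beta, smooth muscle, pericyte and enteric glia and neuron lists. They also included the enteroendocrine, YAP, squamous, erythroid, mTORC1 and ATF4, and ribosomal protein lists. The scores of every other list had an exact permutation p of at least 0.0571. In 25 lists no tested member passed in edgeR. Of their 337 members, 73 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 36 and 1.

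**Figure D1:**
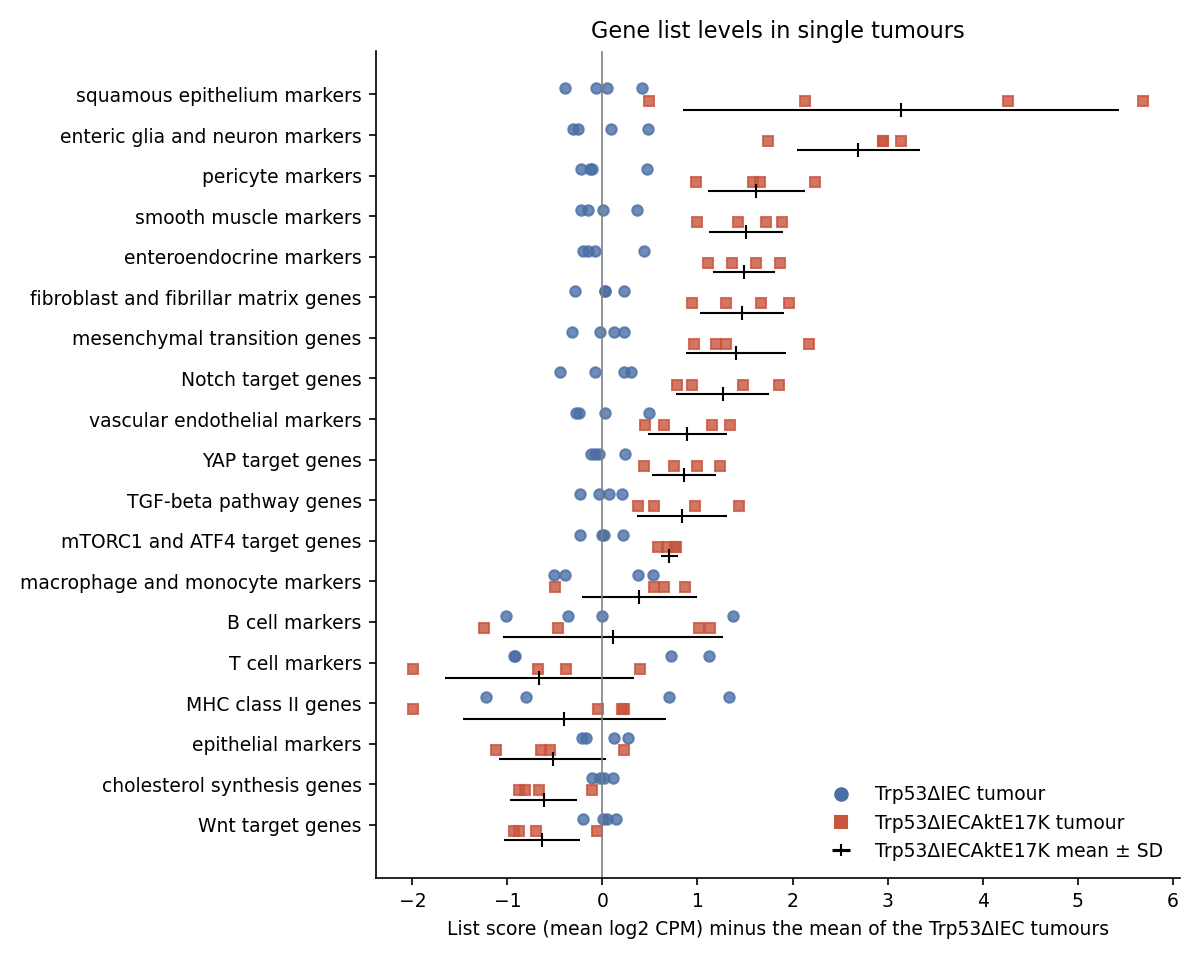
Each row is a gene list, the x axis is its score in single tumours (mean log2 CPM of the members) minus the mean of the Trp53ΔIEC tumours, circles and squares are Trp53ΔIEC and Trp53ΔIECAktE17K tumours, and black marks give the Trp53ΔIECAktE17K mean ± SD. The group difference is 2.69 for enteric glia and neuron markers, 1.51 for smooth muscle markers, 1.26 for Notch target genes and 3.14 for squamous epithelium markers, whose scores are the most spread over the Trp53ΔIECAktE17K tumours (SD 2.29), whereas the scores of B cell markers overlap.

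Trp53, Akt1 and Akt2 did not pass the test for a difference in their total level. Trp53, the tumour suppressor, had 24.0 ± 2.19 CPM in Trp53ΔIEC and 29.0 ± 5.79 CPM in Trp53ΔIECAktE17K tumours (adjusted p = 0.407). Akt1, the kinase gene, had 397.5 ± 22.2 and 371.3 ± 30.6 CPM (adjusted p = 0.670). Akt2 had a log2 fold change of -0.16 (adjusted p = 0.522). Counts per gene in whole tumours mix epithelium with other cells and do not show alleles, so they cannot check either genotype.

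Notch3 (ENSMUSG00000038146, chromosome 17, 32120820 to 32166852, minus strand, mm10), a receptor of pericytes and vascular smooth muscle among other cells, rose by a log2 fold change of 1.65 ± 0.36 (SE, adjusted p = 0.0434). Its level was 12.4, 8.69, 8.88 and 9.40 CPM in the Trp53ΔIEC tumours and 56.5, 24.9, 21.5 and 20.3 CPM in the Trp53ΔIECAktE17K tumours. Notch1, the main Notch receptor of the crypt epithelium, had 48.4 ± 7.73 and 40.1 ± 14.0 CPM (adjusted p = 0.622). Notch2 and Notch4 had log2 fold changes of -0.06 and 0.18 (adjusted p = 0.911 and 0.563). In the list of Notch receptors and ligands, Notch3 was the called gene among 8 tested, and it was also the 1 gene called when adjusted over the list alone. The list's median log2 fold change was -0.03 and its mean 0.27, and camera gave an adjusted p of 0.758. The Notch target genes rose as a list (camera adjusted p = 0.00935, adjusted p = 0.340 with an estimated correlation, fry adjusted p = 0.0331). None of its 6 tested members passed in edgeR, where 4 had an unadjusted p under 0.05, 4 passed when adjusted over the list alone, and DESeq2 and limma-voom called 3 and 0. The scores of pericyte and smooth muscle markers differed by 1.62 and 1.51 between the same tumours, so the rise of the Notch target list is not separated from theirs. Nrarp, a feedback inhibitor of Notch signalling, had 15.4 ± 4.56 and 44.6 ± 22.4 CPM (adjusted p = 0.0646). The transcription factor gene Hey2 had 0.840 ± 0.437 and 4.38 ± 4.68 CPM (adjusted p = 0.144). The Notch3 call was lost when any 1 of 6 tumours was left out. Its adjusted p was 0.0725, 0.123, 0.119 and 0.119 without Trp53ΔIEC replicates 1, 2, 3 and 4, and 0.0551 and 0.0806 without Trp53ΔIECAktE17K replicates 1 and 2. Without Trp53ΔIECAktE17K replicate 1 the log2 fold change was 1.15. Limma-voom gave Notch3 an adjusted p of 0.0765 and DESeq2 0.000626. With the letter of the sample title as a term the log2 fold change was 1.09 (adjusted p = 0.206).

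**Figure D2:**
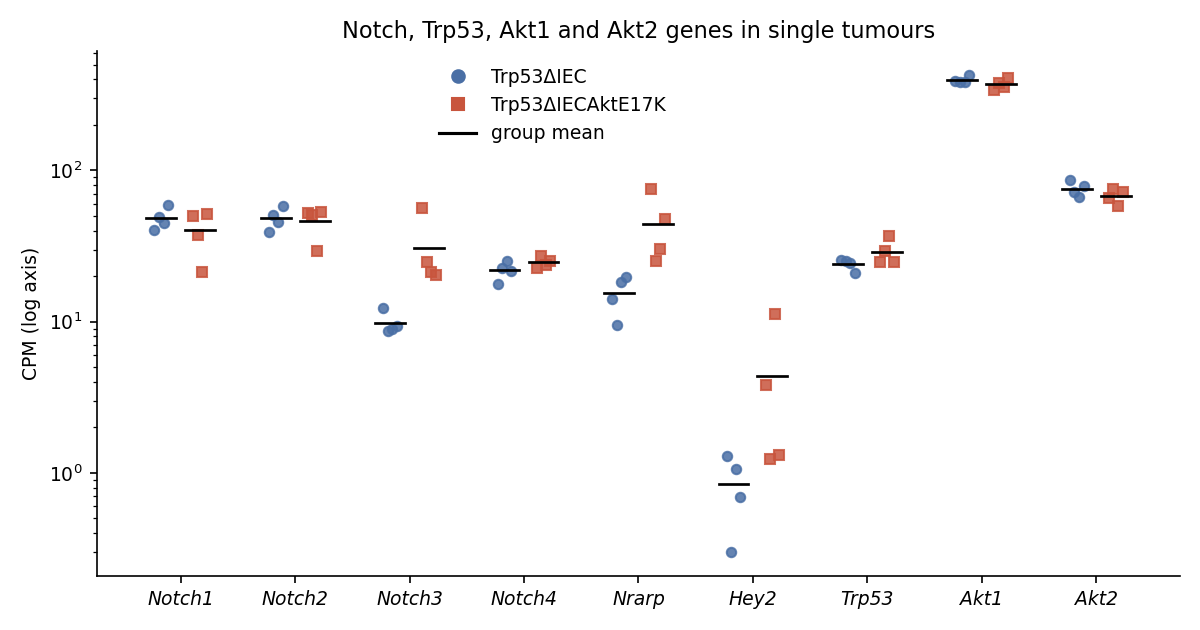
Levels of the Notch receptor, Notch target, Trp53, Akt1 and Akt2 genes in CPM on a log axis, with circles for Trp53ΔIEC tumours, squares for Trp53ΔIECAktE17K tumours and lines for group means. Notch3 lies between 8.69 and 12.4 CPM in the first group and between 20.3 and 56.5 CPM in the second, and the other receptors overlap between groups.

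Of 22 tested fibroblast and fibrillar matrix genes 13 rose and 0 fell, and 18 rose when adjusted over the list alone. Among them were Loxl1, an elastin crosslinking enzyme (15.3 ± 2.20 against 83.8 ± 28.1 CPM), and Thbs2 (16.7 ± 9.75 against 172.3 ± 69.1 CPM). The microfibril genes Fbn1 and Mfap5 rose by log2 fold changes of 1.77 and 4.61. Of 17 mesenchymal transition genes 5 rose, and 11 higher and 1 lower passed when adjusted over the list alone. Lox (ENSMUSG00000024529, chromosome 18, 52516067 to 52529867, minus strand), a collagen crosslinking enzyme, rose from 34.9 ± 6.0 to 166.5 ± 40.2 CPM (adjusted p = 0.00387). The transcription factor genes Prrx1 and Snai1 and the N-cadherin gene Cdh2 rose by log2 fold changes of 4.11, 1.26 and 4.02. Camera's adjusted p was 9.88e-18 for the fibroblast list and 2.86e-09 for the mesenchymal list (adjusted p = 0.186 and 0.156 with an estimated correlation, fry 0.0175 and 0.0135). The scores differed by 1.47 and 1.41 on the log2 scale. Lox and Loxl1 stayed called without any 1 of the 8 tumours. Without Trp53ΔIEC replicate 2, 3 or 4 the adjusted p was up to 0.0638 for Prrx1, 0.0586 for Fbn1 and 0.0657 for Mfap5, and without replicate 2 or 3 it was up to 0.0650 for Thbs2. Cdh2 and Snai1 lost their calls in 5 and 7 of the 8 removals (up to 0.0846 and 0.113).

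Smooth muscle markers rose in 8 of 14 tested members, in 12 when adjusted over the list alone. Cnn1 (ENSMUSG00000001349, chromosome 9, 22099216 to 22109630, plus strand), which encodes the contractile protein calponin, rose from 12.3 ± 2.99 to 108.2 ± 30.02 CPM (adjusted p = 0.00189). Des, the intermediate filament gene of muscle, rose from 15.9 ± 4.53 to 222.1 ± 73.2 CPM. Tagln rose from 69.1 ± 17.6 to 335.3 ± 81.9 CPM and the enteric actin gene Actg2 from 37.2 ± 12.0 to 207.0 ± 55.7 CPM. All 4 genes stayed called without any 1 tumour. Pericyte markers rose in 4 of 9 (7 over the list alone), with the potassium channel genes Kcnj8 and Abcc9 at log2 fold changes of 2.53 and 2.03, Higd1b at 2.11 and Ndufa4l2 at 4.16. For smooth muscle and pericyte lists camera's adjusted p was 1.76e-18 and 9.72e-08 (adjusted p = 0.156 and 0.227 with an estimated correlation, fry 0.0131 and 0.0221). Vascular endothelial markers rose as a list (camera adjusted p = 8.28e-06, adjusted p = 0.438 with an estimated correlation). Among 15 of them Plvap was called (60.4 ± 12.6 against 112.4 ± 20.2 CPM), and 9 were called when adjusted over the list alone. Lymphatic endothelial markers rose as a list (camera adjusted p = 0.0373, adjusted p = 0.438 with an estimated correlation) with Pdpn called (log2 fold change 1.05), 2 of 6 over the list alone. The 4 pericyte genes, Plvap and Pdpn each lost their call in 3 to 7 of the 8 removals, with adjusted p values of up to 0.0664 (Kcnj8), 0.0765 (Abcc9), 0.117 (Higd1b), 0.118 (Ndufa4l2), 0.121 (Plvap) and 0.0994 (Pdpn). Without Trp53ΔIECAktE17K replicate 1 the log2 fold change of Ndufa4l2 was 3.03. The lymphatic list kept its call in 2 removals and had adjusted p values of 0.0646, 0.0620 and 0.0634 without Trp53ΔIEC replicates 1, 2 and 4 and 0.113, 0.0599 and 0.105 without Trp53ΔIECAktE17K replicates 1, 2 and 4.

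TGF-beta pathway genes rose as a list (camera adjusted p = 0.00218, adjusted p = 0.480 with an estimated correlation, fry 0.103). Without both Trp53ΔIECAktE17K replicates 1 and 4 camera's adjusted p for this list was 0.0516. Ltbp2, which binds fibrillin, rose from 6.32 ± 0.546 to 76.2 ± 37.7 CPM and Ccn2 from 64.8 ± 16.2 to 321.4 ± 141.0 CPM. They were the called genes among 14, and 5 were called when adjusted over the list alone. YAP target genes rose as a list (camera adjusted p = 0.00118, adjusted p = 0.307 with an estimated correlation, fry 0.0329). Of 12 members 2 were called, Ccn2 and Ankrd1 (log2 fold change 3.04), the same number as over the list alone. Matrix proteases and their inhibitors rose as a list (camera adjusted p = 0.00825, adjusted p = 0.571 with an estimated correlation, and 0.0536 without Trp53ΔIEC replicate 3). The protease list score had an exact permutation p of 0.114. Mmp3, a stromelysin, rose from 7.56 ± 6.64 to 107.6 ± 36.6 CPM and the neutrophil collagenase gene Mmp8 from 1.33 ± 1.06 to 10.2 ± 5.35 CPM. They were the called genes among 17, and 5 were called over the list alone. None of 12 basement membrane genes passed in edgeR (4 at an unadjusted p under 0.05, 3 over the list alone, 1 by DESeq2, 0 by limma-voom). Camera's adjusted p was 0.0881, or 0.0236 without Trp53ΔIEC replicate 1 and 0.0176 without Trp53ΔIECAktE17K replicate 3. Hspg2 and Lama4 had log2 fold changes of 0.95 and 0.68 (adjusted p = 0.0576 and 0.121). Ltbp2 stayed called without any 1 tumour, whereas Ccn2, Ankrd1 and Mmp3 lost their calls in 3, 5 and 5 removals (up to 0.0733, 0.0893 and 0.0870) and Mmp8 in all 8 (up to 0.116). The log2 fold change of Ankrd1 was 2.42 without Trp53ΔIECAktE17K replicate 2, that of Mmp3 4.46 without Trp53ΔIEC replicate 1 against 3.82, and that of Mmp8 3.63 without Trp53ΔIEC replicate 2 against 2.93.

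Markers of enteric glia and neurons rose in 5 of 9 tested members (7 over the list alone, camera adjusted p = 1.23e-10, adjusted p = 0.156 with an estimated correlation, fry 0.0101). Uchl1, a neuronal ubiquitin hydrolase gene, rose from 3.07 ± 0.708 to 21.5 ± 7.29 CPM and stayed called without any 1 tumour. Sox10, a glial transcription factor gene, had 0 counts in the Trp53ΔIEC tumours and 1.61 ± 0.786 CPM in the others, at least 50.9-fold higher. Prph and Snap25 rose by log2 fold changes of 4.71 and 2.89. Enteroendocrine markers rose as a list (camera adjusted p = 2.71e-05, adjusted p = 0.156 with an estimated correlation, fry 0.0131). The somatostatin gene Sst was called among 12 (0.248 ± 0.208 against 2.3 ± 1.57 CPM), and 8 were called over the list alone. The neuropeptide gene Cartpt had 0 counts in Trp53ΔIEC and 7.20 ± 6.93 CPM in Trp53ΔIECAktE17K tumours, at least 230-fold higher (adjusted p = 0.0384). Of 8 tuft cell markers 1 rose, Pou2f3, the master regulator of that cell type (0.157 ± 0.0648 against 3.97 ± 4.25 CPM). The number was the same over the list alone, and camera's adjusted p was 0.636. Calls were lost in some removals for Sox10 (adjusted p up to 0.0702), Prph (0.0843), Snap25 (0.0893), Sst (0.119), Cartpt (0.0857) and Pou2f3 (0.0943). The log2 fold change was 5.75 for Prph without Trp53ΔIEC replicate 2, and 3.59 instead of 4.63 for Pou2f3 without Trp53ΔIECAktE17K replicate 3. For Sst it was 3.20, but 3.95 without Trp53ΔIEC replicate 4 and 2.61 without Trp53ΔIECAktE17K replicate 1. Cartpt was at 16.7 CPM in Trp53ΔIECAktE17K replicate 2 and at 1.02 to 7.77 CPM in the other 3.

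Squamous epithelium markers rose in 4 of 12 tested members, in 7 over the list alone, and as a list (camera adjusted p = 0.00104, adjusted p = 0.485 with an estimated correlation, fry 0.167). Krt5 (ENSMUSG00000061527, chromosome 15, 101707070 to 101712898, minus strand), the basal keratin gene, had 0.247 ± 0.313 CPM in Trp53ΔIEC and 1340 ± 2194 CPM in Trp53ΔIECAktE17K tumours (log2 fold change 12.29 ± 2.47, SE, adjusted p = 0.0361). Its level was 4606, 121.5, 2.35 and 629.9 CPM in Trp53ΔIECAktE17K replicates 1 to 4, so that the mean rests on replicates 1 and 4. Krt6a, Krt6b, Krtdap and Trp63, the basal cell transcription factor gene, rose by log2 fold changes of 7.03, 10.52, 8.52 and 7.86, and limma-voom called 0 of the 12 markers. The binding protein gene Igfbp2 rose from 1.59 ± 0.705 to 549.5 ± 929.9 CPM (log2 fold change 8.41, adjusted p = 0.0323), with 175.4, 58.8, 1941 and 22.8 CPM in Trp53ΔIECAktE17K replicates 1 to 4. The mean rests on replicate 3, without which the log2 fold change was 5.73. The growth factor gene Gdf10 rose by a ratio of counts of 354 (95% interval 121 to 1721, adjusted p = 0.0232). These calls were lost in 4 or more removals, among them that of each Trp53ΔIEC tumour, with adjusted p values of up to 0.108 (Krt5), 0.0857 (Krt6a), 0.121 (Krt6b), 0.124 (Krtdap), 0.125 (Trp63), 0.104 (Igfbp2) and 0.0827 (Gdf10). Without Trp53ΔIECAktE17K replicate 1 the log2 fold changes of Krt5, Krt6a, Krt6b, Krtdap, Trp63 and Gdf10 were 9.85, 5.51, 8.85, 7.86, 6.27 and 6.80. Without Trp53ΔIEC replicate 2 those of Krt5 and Trp63 were 13.75 and 8.79, and without replicate 3 of that group that of Krtdap was 11.34.

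In a list of 36 heart muscle genes, written after the data had been seen, 25 of the 34 tested rose. The list summed to 704.4 to 805 CPM in Trp53ΔIEC and 1148 to 1374 CPM in Trp53ΔIECAktE17K tumours. Myh6 (ENSMUSG00000040752, chromosome 14, 54941921 to 54966927, minus strand), the alpha myosin heavy chain gene of the heart, rose from 0.0748 ± 0.101 to 53.5 ± 4.42 CPM (log2 fold change 9.54 ± 0.58, SE, adjusted p = 0.000818). Myl3, a ventricular myosin light chain gene, had 0 counts in Trp53ΔIEC tumours and 6.69 ± 1.35 CPM in the others, at least 206-fold higher (adjusted p = 0.00414). In the list of skeletal muscle markers, too few of which were tested for a set test, 2 of 4 rose, also over the list alone. Mb, the myoglobin gene, rose from 0.377 ± 0.294 to 15.4 ± 1.32 CPM and Ckm from 0.176 ± 0.0963 to 3.54 ± 0.848 CPM, and both are also expressed in heart. Myh6, Myl3, Mb and Ckm stayed called without any 1 tumour, and the log2 fold change of Myh6 was 10.68 without Trp53ΔIEC replicate 3.

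Hepatocyte genes, also listed after the data had been seen, went both ways. Of 30 tested 10 fell and 1 rose, the haptoglobin gene Hp, chosen after its values were seen (14.7 ± 7.52 against 134.9 ± 97.3 CPM, adjusted p = 0.0266). All 35 measured genes together summed to 210.3 to 257.4 CPM in Trp53ΔIEC and to 384.5 to 587.4 CPM in Trp53ΔIECAktE17K tumours. Crp (ENSMUSG00000037942, chromosome 1, 172698055 to 172833031, plus strand), the acute phase protein gene of the liver, had 5.11 ± 0.388 CPM in Trp53ΔIEC and 0.0106 ± 0.0212 CPM in Trp53ΔIECAktE17K tumours. The ratio of counts was 476 (95% interval 85.02 to 18840, adjusted p = 0.00135), and the 1 count of the second group lay in its replicate 1. Mup5, a major urinary protein gene, and the pseudogene Cyp2c53-ps had 0 counts in Trp53ΔIECAktE17K tumours and were at least 148-fold and 131-fold lower there (4.74 ± 1.17 and 4.14 ± 0.867 CPM in Trp53ΔIEC tumours). Pzp, Itih4 and the haem carrier gene Hpx fell by 3.60, 3.12 and 2.91 on the log2 scale, Hpx from 12.1 ± 0.384 to 1.61 ± 0.823 CPM. Crp, Mup5, Cyp2c53-ps, Pzp and Hpx stayed called without any 1 tumour, and Itih4 lost its call in the removal of each Trp53ΔIEC tumour (adjusted p up to 0.0766). The albumin gene Alb, chosen after its values were seen, had 25.7 ± 6.21 and 5.18 ± 3.57 CPM (adjusted p = 0.0866). Among the other genes with the largest decreases, the meiotic cohesin gene Rec8 fell from 98.8 ± 36.6 to 2.38 ± 3.92 CPM (log2 fold change -5.39, adjusted p = 0.0454, and -7.83 without Trp53ΔIECAktE17K replicate 4). The complement regulator gene C4bp fell by 3.45 and Acss3 fell by 2.83 on the log2 scale. These calls were lost in 6, 5 and 7 removals (up to 0.115, 0.0801 and 0.104).

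**Figure D3:**
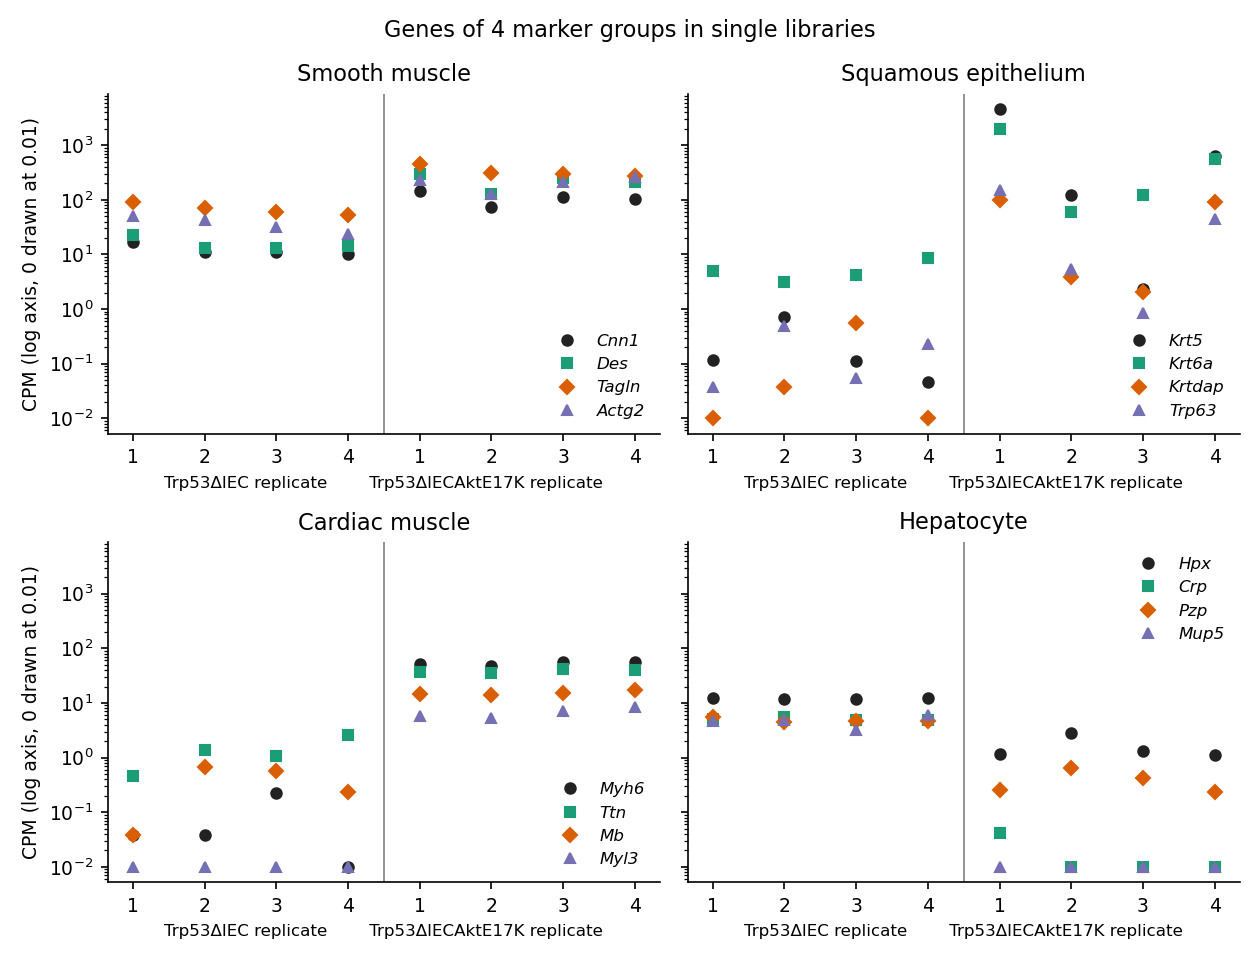
Levels in CPM on a log axis (0 drawn at 0.01) of 4 genes each from smooth muscle, squamous epithelium, cardiac muscle and hepatocytes, with 1 position per library and a line between Trp53ΔIEC and Trp53ΔIECAktE17K libraries. Krt5 runs from 2.35 to 4606 CPM over the Trp53ΔIECAktE17K libraries, while Myh6 (53.5 ± 4.42 CPM) and, in the Trp53ΔIEC libraries, Hpx (12.1 ± 0.384 CPM) are nearly level.

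Of the other minority cell types, adipocyte markers had 3 tested members, too few for a set test, of which Fabp4 rose (6.76 ± 1.64 against 40.2 ± 23.3 CPM), also over the list alone. Of the 5 tested erythroid genes 4 rose and 1 fell, with the same numbers over the list alone (camera adjusted p = 0.000255, adjusted p = 0.350 with an estimated correlation, fry 0.0329). The haem synthesis gene Alas2 and the globin genes Hbb-bt and Hba-a1 rose by log2 fold changes of 2.56, 2.88 and 3.23. Hba-a2, whose sequence is almost that of Hba-a1, fell, with 115 counts in Trp53ΔIEC and 2 in Trp53ΔIECAktE17K tumours, a ratio of 57.6 (95% interval 15.6 to 481.5). Its log2 fold change was -5.50, or -4.88 without Trp53ΔIEC replicate 1. Calls were lost in 3 removals for Fabp4 and Alas2 (adjusted p up to 0.0761 and 0.0621) and in 5 for Hba-a2, Hbb-bt and Hba-a1 (up to 0.0724, 0.0788 and 0.0815).

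Among 8 tested cytotoxic cell markers Gzma, a granule protease gene, rose from 0.878 ± 0.760 to 8.90 ± 4.91 CPM (1 over the list alone, camera adjusted p = 0.292). It lost its call in 7 removals (adjusted p up to 0.131), and its log2 fold change of 3.34 was 4.11 without Trp53ΔIEC replicate 4. Of 14 T cell markers 0 passed in edgeR, 0 had an unadjusted p under 0.05 and DESeq2 and limma-voom called 0. Camera placed the T cell list lower (adjusted p = 0.0451, adjusted p = 0.740 with an estimated correlation). The adjusted p was 0.193 and 0.337 without Trp53ΔIEC replicates 2 and 3, and 0.0520, 0.103 and 0.375 without Trp53ΔIECAktE17K replicates 1, 2 and 3. It was 0.0502 with DESeq2's size factors and 0.111 with a term for the replicate number. The receptor gene Trac had a log2 fold change of -1.22 (adjusted p = 0.304). The 10 B cell, 8 plasma cell, 10 MHC class II and 10 MHC class I presentation genes likewise gave 0 calls in edgeR, DESeq2 and limma-voom and 0 unadjusted p under 0.05. Their camera adjusted p values were 0.976, 0.470, 0.255 and 0.239. Camera placed the B cell list lower although its median log2 fold change was 0.03. The MHC class II list had an adjusted p of 0.0252 without Trp53ΔIEC replicate 1, and the MHC class I list 0.0184 without Trp53ΔIEC replicate 3 and 0.0382 without Trp53ΔIECAktE17K replicate 3. In these lists Pax5 and Fcer2a had log2 fold changes of 1.11 and -0.63, Sdc1 and Derl3 of 0.42 and 1.2, Ciita and Cd74 of -1.28 and -0.87, and H2-K1 and Tap2 of 0.64 and 0.58.

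Inflammatory cytokines and chemokines rose as a list (camera adjusted p = 0.00104, adjusted p = 0.562 with an estimated correlation), with 2 of 19 called and 7 over the list alone. Il6 rose from 0.551 ± 0.228 to 22.2 ± 27.5 CPM (log2 fold change 5.30), with 62.9 CPM in Trp53ΔIECAktE17K replicate 2 and 3.82 to 14.0 CPM in the other 3, and without replicate 2 the log2 fold change was 3.91. The granulocyte growth factor gene Csf3 rose from 0.395 ± 0.389 to 7.10 ± 6.08 CPM (log2 fold change 4.13, and 3.30 without the same tumour or 5.11 without Trp53ΔIEC replicate 2). Neutrophil markers rose as a list (camera adjusted p = 0.00115, adjusted p = 0.485 with an estimated correlation, and 0.0552 without Trp53ΔIECAktE17K replicate 4). Of 13 members 2 were called, Mmp8 and the antimicrobial peptide gene Camp (ratio of counts 92.8, 95% interval 16.2 to 3705, with the 1 count of the Trp53ΔIEC tumours in replicate 3), and 3 over the list alone. Interferon response genes rose as a list (camera adjusted p = 0.000918, adjusted p = 0.573 with an estimated correlation). Their scores overlapped between the groups, and Trp53ΔIEC replicate 1 (3.73) lay far below the rest of its group (5.94 to 6.29). Of 19 members 0 passed in edgeR, 9 had an unadjusted p under 0.05, 1 passed over the list alone, and DESeq2 and limma-voom called 3 and 0. Mx1 and Oas2 had log2 fold changes of 1.57 and 1.45 (adjusted p = 0.0545 and 0.116). Mast cell and eosinophil markers were lower as a list (camera adjusted p = 0.0226, adjusted p = 0.567 with an estimated correlation, and 0.0888 and 0.0878 without Trp53ΔIEC replicate 1 and Trp53ΔIECAktE17K replicate 3). Of 9 members 0 were called in edgeR, 2 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 1 and 0. The protease gene Cma1 had a log2 fold change of -1.59 and Kit of 2.41. Of 15 macrophage and 9 dendritic cell markers 0 passed in edgeR, 3 and 1 had an unadjusted p under 0.05, DESeq2 called 2 and 1 and limma-voom 0. Camera's adjusted p was 0.25 and 0.116. Without Trp53ΔIEC replicate 3 and without Trp53ΔIECAktE17K replicate 3 the macrophage list reached 0.0361 and 0.00617, and without Trp53ΔIEC replicates 1 and 4 the dendritic list reached 0.0217 and 0.0308. Arg1 had 24.0 ± 11.4 and 135.6 ± 124.1 CPM (adjusted p = 0.0753), Trem2 a log2 fold change of 1.24, and the dendritic genes Xcr1 and Zbtb46 of -2.51 and 0.53. Il6, Csf3 and Camp lost their calls in 5, 6 and 2 removals (adjusted p up to 0.0871, 0.102 and 0.0530). The scores of the inflammatory, neutrophil, interferon and mast cell lists had exact permutation p values of 0.0857, 0.0857, 0.171 and 0.171.

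Epithelial markers were lower as a list (camera adjusted p = 0.00115, adjusted p = 0.510 with an estimated correlation). Of 18 members 0 were called in edgeR, 6 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 3 and 0. The score difference of -0.52 did not pass the exact permutation test (p = 0.143). The splicing factor gene Esrp1 and the brush border gene Vil1 had log2 fold changes of -0.49 and -1.21 (adjusted p = 0.107 and 0.138). Ascl2, a stem cell transcription factor gene, fell from 42.6 ± 8.42 to 11.0 ± 5.27 CPM (adjusted p = 0.0463). The ion transporter gene Slc12a2 fell from 427.8 ± 135.5 to 197.8 ± 30.1 CPM (adjusted p = 0.0472). They were the called genes among 13 stem cell markers, where 1 higher and 3 lower passed over the list alone. Camera gave the list 0.0615 and fry 0.0329, with a median log2 fold change of -0.33 and a mean of 0.01. Camera's adjusted p for the stem cell list was 0.0422, 0.0402, 0.0392 and 0.0284 without Trp53ΔIEC replicates 1 and 2 and without Trp53ΔIECAktE17K replicates 1 and 3, and 0.0273 with no low-count filter. Wnt target genes were lower as a list (camera adjusted p = 0.00115, adjusted p = 0.350 with an estimated correlation), with Ascl2 called among 16 and 2 lower over the list alone. Goblet cell markers rose as a list (camera adjusted p = 0.0161, adjusted p = 0.573 with an estimated correlation, and 0.0849 and 0.307 without Trp53ΔIEC replicate 2 and Trp53ΔIECAktE17K replicate 4). The goblet list score had an exact permutation p of 0.171. The transcription factor gene Spdef was called among 12 (10.2 ± 2.27 against 30.1 ± 13.1 CPM), also over the list alone. Ascl2, Slc12a2 and Spdef lost their calls in 7, 6 and 7 removals (adjusted p up to 0.118, 0.120 and 0.129).

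Colonocyte markers went both ways, with 1 of 16 higher and 1 lower (2 and 1 over the list alone, camera adjusted p = 0.976). The guanylin gene Guca2a rose from 28.3 ± 10.8 to 134.0 ± 63.9 CPM. The sodium-proton exchanger gene Slc9a3 fell from 43.5 ± 16.8 to 2.73 ± 1.47 CPM (adjusted p = 0.0134, and 0.0504 without Trp53ΔIEC replicate 2). Of 12 regenerative and fetal genes the osteopontin gene Spp1 rose (52.0 ± 29.9 against 509.9 ± 493.4 CPM, the same number over the list alone). Its log2 fold change was 3.29, or 2.37 without Trp53ΔIECAktE17K replicate 2. Camera's adjusted p was 0.624, or 0.0350 without Trp53ΔIECAktE17K replicate 3. Guca2a and Spp1 lost their calls in 4 and 7 removals (adjusted p up to 0.0906 and 0.138). Of 9 Paneth-like secretory markers 0 passed in edgeR, 3 had an unadjusted p under 0.05 and DESeq2 and limma-voom called 3 and 0. The list's median log2 fold change was 0.51, while camera placed it lower (adjusted p = 0.743). Pla2g2a had 222.6 ± 107.7 and 1944 ± 2160 CPM (adjusted p = 0.176).

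Targets of mTORC1 and ATF4 rose as a list (camera adjusted p = 1.86e-05, adjusted p = 0.156 with an estimated correlation, fry 0.0101), with 4 of 16 called and 8 over the list alone. Slc7a5 and Slc3a2, which encode the 2 chains of an amino acid transporter, rose from 99.6 ± 9.30 to 178.4 ± 36.8 CPM and from 152.0 ± 12.8 to 283.5 ± 71.2 CPM. The stress response genes Chac1 and Trib3 rose by log2 fold changes of 1.51 and 2.17. Cholesterol synthesis genes were lower as a list (camera adjusted p = 1.68e-06, adjusted p = 0.411 with an estimated correlation, fry 0.0619), with 2 of 18 fallen and 3 over the list alone. Srebf2, the transcriptional regulator of the pathway, fell from 471.4 ± 54.5 to 264.9 ± 42.2 CPM. The score difference of -0.62 had an exact permutation p of 0.0571. Slc7a5, Slc3a2, Chac1, Trib3 and Srebf2 lost their calls in 5 to 7 removals, with adjusted p values of up to 0.0911 (Slc7a5), 0.118 (Slc3a2), 0.108 (Chac1), 0.129 (Trib3) and 0.0817 (Srebf2).

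Hypoxia genes rose as a list (camera adjusted p = 0.00542, adjusted p = 0.444 with an estimated correlation, and 0.0549 without Trp53ΔIECAktE17K replicate 1), as did glycolysis genes (0.0262, adjusted p = 0.567 with an estimated correlation). Without Trp53ΔIEC replicate 1 and Trp53ΔIECAktE17K replicates 1, 3 and 4 the glycolysis list had adjusted p values of 0.0777, 0.0574, 0.0529 and 0.0647. In these lists 0 of 14 and 0 of 16 genes passed in edgeR, 5 and 5 had an unadjusted p under 0.05, DESeq2 called 2 and 3, limma-voom 0, and 1 and 0 passed over the list alone. P4ha1 and Adm had log2 fold changes of 0.78 and 1.3, and the glucose transporter gene Slc2a1 and Ldha of 0.95 and 0.51. Genes of fatty acid synthesis and targets of FOXO, a transcription factor family that AKT restrains, had camera adjusted p values of 0.134 and 0.123. Of 12 and 17 members 0 were called in edgeR, 3 and 6 had an unadjusted p under 0.05, DESeq2 called 0 and 4 and limma-voom 0 and 1. Elovl5 and Fads2 had log2 fold changes of -0.55 and -0.91, the insulin receptor substrate gene Irs2 of -1.28 (adjusted p = 0.0615) and Trib1 of -0.50. Of 21 p53 target genes 0 passed in edgeR, 5 had an unadjusted p under 0.05, DESeq2 called 4 and limma-voom 0 (camera adjusted p = 0.315). Eda2r and Ephx1 had log2 fold changes of 1.86 and 1.77.

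Ribosomal protein genes rose as a list (camera adjusted p = 0.00614, adjusted p = 0.694 with an estimated correlation, and 0.119 without Trp53ΔIECAktE17K replicate 3). Of 22 members 0 were called in edgeR, 7 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 1 and 0. Rplp2 and Rpl13 had log2 fold changes of 0.67 and 0.47. G2/M cell cycle genes were lower as a list (camera adjusted p = 0.0483, adjusted p = 0.808 with an estimated correlation). That call was lost without Trp53ΔIEC replicates 3 and 4 (0.120 and 0.422) and without Trp53ΔIECAktE17K replicates 1 and 4 in turn (0.226 and 0.307). Without both of the latter the direction was reversed (adjusted p = 0.832). Of 21 G2/M and 18 G1/S genes 0 passed in edgeR or DESeq2 or limma-voom, and 3 and 0 had an unadjusted p under 0.05. Kif20a and Kif23 had log2 fold changes of -0.63 and -0.70, and Ccne1, of the G1/S list (camera adjusted p = 0.737), of 0.59. Without both Trp53ΔIECAktE17K replicates 1 and 4 camera called the G1/S list higher (adjusted p = 0.00751). Respiratory chain genes (19 tested, camera adjusted p = 0.533) and genes of colonic xenobiotic and sulphur metabolism (16 tested, 0.591) had 0 calls in edgeR, 1 and 5 unadjusted p under 0.05, 0 and 4 calls by DESeq2 and 0 by limma-voom. Cox6c and Ndufa4 had log2 fold changes of 0.43 and -0.50, and Cyp2c65 and Sult1c2 of 2.37 and 1.95, with 1 gene of the metabolism list called over the list alone.

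Among 13 immediate early genes the phosphatase gene Dusp1 rose from 32.9 ± 6.11 to 66.9 ± 18.4 CPM (1 over the list alone, lost in 6 removals with an adjusted p of up to 0.119). Camera placed the list lower (adjusted p = 0.792) and fry higher (0.983). Of 11 heat shock genes 0 passed in edgeR, 1 had an unadjusted p under 0.05, DESeq2 called 1 and limma-voom 0. Camera placed that list lower (adjusted p = 0.857), in sign with its median log2 fold change of -0.05 and against its mean of 0.15. Hspb1 and Hspa8 had log2 fold changes of 1.58 and -0.37. Of the sex chromosome genes Xist was tested, with a log2 fold change of 1.26 (adjusted p = 0.616).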

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

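The counts under other splits of the samples and the tests of heart or liver reads, of other cells, of a batch by title letter, of the epithelial share, of muscle wall and of squamous lining were chosen after the results were seen.

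Of the 35 splits of the 8 tumours into 2 groups of 4, only 1, the real one, called as many as 694 genes in edgeR. The highest other split called 0 genes, with up to 2523 at an unadjusted p under 0.05 in a split. For lists called by fry 1 split reached the real 11 and the highest other had 2. The real split thus ranked first for both, the most that 35 splits can show, which does not exclude chance. The other splits mix the 2 genotypes, so a genotype difference adds to their spread, which can lower their counts. For lists called by camera 5 splits had at least the real 28, and the highest other had 33.

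Of 158 groups of 4 tumours examined, 13 held a tumour far from the other 3 for its group's range, where chance gives about 1 in 20, or 7.9. Some concern list scores (mean log2 CPM). Trp53ΔIEC replicate 1 was above its group for pericyte markers (3.32) and below it for interferon response genes (3.73). Trp53ΔIEC replicate 4 was above its group for immediate early genes (5.86). Trp53ΔIECAktE17K replicate 2 was above its group for cytotoxic cell markers (1.98) and below it for FOXO target genes (4.995). Trp53ΔIECAktE17K replicate 3 was below its group for dendritic cell markers (0.44) and MHC class II genes (2.77). Trp53ΔIECAktE17K replicate 4 was below its group for enteric glia and neuron markers (1.55). Others concern log2 CPM of single genes. Trp53ΔIECAktE17K replicate 3 was below its group for Notch2 (4.88), and replicate 2 of that group above it for Hpx (1.55). Trp53ΔIEC replicate 3 had no count of Gdf10 (-3.53, which rests on the prior count), and Trp53ΔIECAktE17K replicate 1 had the 1 count of Crp in its group (-2.96). Immunoglobulin segments took 1.95% of the assigned reads of Trp53ΔIECAktE17K replicate 4 and 0.146% to 0.404% in the rest of its group. In the counts of reads not assigned to genes, alignments of reads with several places in the genome were more frequent in Trp53ΔIECAktE17K tumours, with a mean of 0.806 ± 0.0795 per assigned read against 0.710 ± 0.0207 (exact permutation p = 0.0286).

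Cardiac transcripts and a part of the hepatocyte transcripts differed between the groups. Of 36 cardiac genes 25 of the 34 tested rose in Trp53ΔIECAktE17K tumours. The other tumours had at least 1 CPM of 13 of the 36, whose source was not tested, and the list's sums were 704.4 to 805 CPM in Trp53ΔIEC and 1148 to 1374 CPM in Trp53ΔIECAktE17K tumours. The most abundant of the 21 tested genes under 1 CPM in Trp53ΔIEC tumours were, in the other group, Myh6 (53.5 ± 4.42 CPM), Actc1 (34.9 ± 3.27 CPM), Hspb7 (18.9 ± 6.68 CPM), Mb (15.4 ± 1.32 CPM) and Myl2 (mean 10.4 CPM). Fabp3 reached 1.26 ± 0.300 CPM there, and Cox7a1 had 5.47 ± 1.49 CPM in Trp53ΔIEC and 5.22 ± 1.23 CPM in Trp53ΔIECAktE17K tumours. Of 35 hepatocyte genes 10 of the 30 tested fell in Trp53ΔIECAktE17K tumours and 1, Hp, rose (14.7 ± 7.52 against 134.9 ± 97.3 CPM), and 16 of the 35 had at least 1 CPM there. The list's sums ran the other way from the 10 genes, with 210.3 to 257.4 CPM in Trp53ΔIEC and 384.5 to 587.4 CPM in Trp53ΔIECAktE17K tumours. Among the list's most abundant genes Tat had 37.7 CPM in Trp53ΔIEC and 32.1 CPM in Trp53ΔIECAktE17K tumours (adjusted p = 0.865) and Alb 25.7 ± 6.21 and 5.18 ± 3.57 CPM (adjusted p = 0.0866). Of the called genes that were lower in the second group Hpx (12.1 ± 0.384 CPM), Itih4 (5.73 CPM) and Crp (5.11 ± 0.388 CPM) were the most abundant in the first, while Apoa1 had 0.960 ± 1.14 and 1.05 ± 1.34 CPM. In comparison lists, 0 of 3 tested kidney genes, 2 of 10 brain genes and 0 of 4 lung genes were called in edgeR.

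Reads of a heart or a liver library are candidate sources that stay open: the called cardiac genes varied little between the 4 libraries (median coefficient of variation 15.6%, against 45.4% for 478 other called genes at similar levels), as did the lower hepatocyte genes (12.9% against 27.8% for 20 genes), but 73.5% and 33.3% of the tested genes of the lists were called that way. Cox7a1 and Apoa1, which did not pass the test, and the risen Hp could not be weighed against a heart or liver profile, since none was used here. Cardiac-like or hepatocyte-like cells in shares that vary as other minority cells do stay open too. Highest-to-lowest ratios over 4 libraries were 1.13 and 1.16 for the genes under 1 CPM in the other group (1.2 and 1.22 for the whole lists). The smallest ratios of the smooth muscle, squamous and glial-neuronal lists were 1.64 and 1.67. These ratios cannot decide, because genes so low in one group pass the low-count filter through the other, which favours even levels there. The comparison lists were not chosen that way, and the whole-list sums rest largely on transcripts found in both groups. With the letter of the sample titles as a term, log2 fold changes of the called genes had a median ratio of 0.91 to those without it. Of the 694 genes 92 stayed called, 18 of the 25 cardiac genes and 5 of the 10 lower hepatocyte genes among them. The ratio cannot decide whether a batch that follows the letter is a cause, because the genes were called on the same tumours. In 691 of the 694 the groups did not overlap. In those genes the Trp53ΔIECAktE17K tumours with the letter B therefore already lay apart from the Trp53ΔIEC tumours. Such a selection favours a high ratio. A batch that coincides with the genotype cannot be told apart from it, because no label or library separates them, and an effect of the genotype on these transcripts stays open and was not tested.

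Camera called 3 stromal lists (fibroblast, smooth muscle and pericyte) and the enteric glia and neuron list higher, but not with an estimated correlation (adjusted p = 0.186, 0.156, 0.227 and 0.156), and 0.11 was the smallest p of the list scores after adjustment. The mean stromal score differed by 1.53 on the log2 scale (exact permutation p = 0.0286), while immune lists went both ways, the mean of T cell, B cell, dendritic, macrophage and MHC class II lists by -0.24 (p = 0.686), and of 8 immune cell lists by 0.07 (p = 0.943), from -1.34 for mast cells to 1.45 for neutrophils. A lower share of epithelium, raising every other cell type alike, stays open for the neural and the stromal lists. The neural minus immune score differed by 2.93 (exact permutation p = 0.0286), and by 2.62 over the 8 lists (exact permutation p = 0.0286). Of the 8 taken alone 3 missed 0.05 in the exact permutation test. They were B cells (2.59, exact permutation p = 0.0571), plasma cells (2.26, exact permutation p = 0.0571) and neutrophils (1.25, exact permutation p = 0.171). These differences cannot decide, because the neural list was chosen for this comparison after its scores were seen to separate the groups. Such a choice favours a small p. Stromal minus immune differed by 1.77 with an exact permutation p of 0.0571. More muscle wall in the dissected tissue may also raise smooth muscle and enteric nerves together, and it stays open because the enteric glia and neuron score rose by 2.69 as well, while a stromal response to the AktE17K genotype is also open and was not tested.

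Squamous genes varied widely within the Trp53ΔIECAktE17K tumours, where the list's sum differed 73.2-fold between the highest and lowest library and Krt5 had 4606, 121.5, 2.35 and 629.9 CPM in replicates 1 to 4. Krt14, chosen after its values were seen, had 6552, 257.3, 40.6 and 684.2 CPM there and 23.6 to 151.7 CPM in Trp53ΔIEC tumours (adjusted p = 0.125). Squamous lining of 1 kind, taken along in differing amounts, would keep the ratio of Krtdap to Krt5 alike, but over the 3 libraries with most Krt5, replicates 1, 2 and 4, it was 0.0215, 0.0318 and 0.143, a 6.64-fold difference that rests on replicate 4. Lining from different sites could still give such ratios, so the explanation stays open, as does a squamous change of the tumours with the genotype, which was not tested.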

How the results depend on the processing

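The runs without Trp53ΔIECAktE17K replicates 1 and 4, without the cardiac muscle and hepatocyte genes, with the letter of the sample title as a term, and with the replicate block and an estimated correlation together were chosen after seeing the data. The counts of 569 higher and 125 lower genes stayed within 1.5 times with DESeq2's size factors (518 and 128), upper-quartile factors (593 and 108), library sizes without the 10 most abundant genes (545 and 123), limma-voom (432 and 115), no low-count filter (516 and 84), non-robust dispersions (586 and 126) and without the cardiac muscle and hepatocyte genes (543 and 115). They were 1715 and 764 with DESeq2, which made 81 false calls on simulated data, and 212 and 41 with at least 5 CPM in 4 samples, where 385 of the 694 genes were tested. Thresholds of 0.01 and 0.10 gave 47 and 8, and 980 and 334. Leaving out 1 tumour gave 64 to 702 higher and 10 to 247 lower genes, and without Trp53ΔIECAktE17K replicates 1 and 4 there were 460 and 223. With the letter of the sample title as a term, so that the difference rests on Trp53ΔIECAktE17K replicates 3 and 4, they were 90 and 6, with 92 of the 694 genes kept. With a replicate block they were 48 and 2, with 45 of the 694 genes kept. The block takes up residual degrees of freedom, and tumours with the same number were not more alike than others (r of deviations from the group mean -0.04, 0.01, -0.24 and 0.01, against -0.24 to 0.25 for other numbers, across genes, which are not independent replicates). For DESeq2, the removals, the letter and the block the cause was not tested further. No gene called both in edgeR and under a scaling, test or filter alternative changed sign.

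Camera called 21 to 31 lists, against 28, under the scalings, filters, dispersions, block, letter and removals, 22 at 0.01 and 30 at 0.10. Under the block it no longer called the T cell, lymphatic, mast cell, glycolysis and G2/M lists (adjusted p = 0.111, 0.0658, 0.0521, 0.0557 and 0.0597). With an estimated correlation it called 0 (8 at an unadjusted p under 0.05), or 0 with the block as well (7 unadjusted), and fry called 11 (20 unadjusted). From the main run, the run with an estimated correlation differed only in that setting. The correlation was preset at 0.01, against estimates of -0.04 (stem cell genes) to 0.93 (MHC class II genes). For fibroblast, smooth muscle and Notch target genes the estimates were 0.45, 0.58 and 0.13. Why fry called fewer lists than camera was not tested. The set test of G2/M cell cycle genes was reversed, with an adjusted p of 0.832, without Trp53ΔIECAktE17K replicates 1 and 4, in a range of 0.000157 to 0.845 over its alternatives. In the same run the G1/S list was called higher (camera adjusted p = 0.00751). The TGF-beta, protease, lymphatic, goblet, mast cell, hypoxia and glycolysis lists lost their calls in that run. For Notch3 the log2 fold change was 1.09 to 1.79 and the adjusted p 0.000626 to 0.206 over its alternatives, with 0.0574 at 5 CPM in 4 samples and 0.0750 with the block. Of 1032 values of named genes with 1 tumour left out, 722 stayed on their side of the threshold, 301 lost and 9 gained the call, and of 1641 under other alternatives 1358, 241 and 42. For list tests these were 359, 27 and 14 of 400, and 525, 97 and 19 of 642 with the 1 reversed. A further 36 values could not be had. In simulated data of this depth, with 4 tumours per group and 200 changed genes, edgeR recovered 6% of 2-fold changes. In the tumours 694 genes were called. The Benjamini-Hochberg cut-off is less strict where more genes are changed, so this share may not carry over to them. Changes of that size may still have been missed.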

Other observations

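The genes named here were chosen after their values were seen. Reads at Gt(ROSA)26Sor, the Rosa26 gene, which is annotated with the type antisense, fell from 36.1 ± 6.43 to 20.6 ± 1.33 CPM in the Trp53ΔIECAktE17K tumours (log2 fold change -0.81, adjusted p = 0.0353). The strand of the reads is not recorded, so they cannot be told from reads of transcripts on the other strand. Grem1, a BMP antagonist gene, rose from 16.4 ± 5.17 to 257.3 ± 95.7 CPM (log2 fold change 3.97, adjusted p = 0.00273) and stayed called without any 1 tumour. The neuropeptide gene Vip rose from 0.135 ± 0.151 to 29.6 ± 27.5 CPM (adjusted p = 0.0160), with 68.4 CPM in Trp53ΔIECAktE17K replicate 2 and 5.08 to 27.3 CPM in the other 3. Wt1, a mesothelial gene among others, rose from 2 counts in the 4 Trp53ΔIEC tumours to 429 in the others (0.0210 ± 0.0246 against 4.68 ± 2.88 CPM, adjusted p = 0.0107). The imprinted neighbours H19 and Igf2 did not pass the test, with 19.3 ± 12.99 against 2176 ± 2387 CPM (adjusted p = 0.0519) and 7.89 ± 3.23 against 227.7 ± 322.5 CPM (adjusted p = 0.0621). H19 ranged from 26.9 to 5265 CPM in Trp53ΔIECAktE17K tumours. Y-linked genes summed to 207 CPM, with 0.488 CPM of Xist, in Trp53ΔIEC replicate 2. In the other 7 tumours they summed to at most 0.279 CPM, with 234.6 to 1493 CPM of Xist.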
